A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

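The series profiled accessible chromatin in Saccharomyces cerevisiae by ATAC-seq, in which the Tn5 transposase cuts and tags open DNA. The cells were haploid MATa yeast of the S288c background. Per the labels, the 8 samples form 4 groups of 2 independent experiments: a control strain (CEN4) and a strain whose chromosome IV centromere is flanked by lox sites (CEN4*, called cen4- once Cre recombinase has excised the centromere), each at 0 min and at 180 min after addition of beta-estradiol at 1 uM. Per the labels' protocols, spheroplasts were tagged with Tn5, libraries were amplified by PCR and sequenced as paired-end reads, and base calls were made with RTA 2.7.7 and bcl2fastq 2.20.0.422. The submitters' processing notes name Bowtie2 2.3.4.3, SAMtools, Picard, HOMER, MACS2 2.2.4 and the sacCer3 build, without saying which step each served. Whether reads were shifted for the Tn5 cut is not given in the sources used here.

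The data used were 4 peak lists deposited by the authors, 1 for each of the strain codes 8 and 11 at 0 min and at 180 min with beta-estradiol. The code and the time tag were read from the names of the lists. No label links a code to CEN4 or CEN4*, so the strains are called code 8 and code 11 throughout and no strain was inferred from the peaks. The lists carry no replicate number, and whether both experiments of a group were pooled before peak calling is not given in the sources used here. There were therefore no replicates to compare, no test between conditions was made, and intervals are exact Clopper-Pearson 95% intervals that cover counting error only.

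Each entry of a list is a sub-peak with its summit. The deposited lists give a score per sub-peak, which equalled 10 times its -log10 p, truncated to a whole number, in 100% of sub-peaks. They also give the authors' fold enrichment of the summit over its local background, a linear ratio. The remaining columns hold -log10 of the p-value and of the q-value as deposited by the authors. All 4 columns belong to the authors and were used to describe, rank or filter peaks within a list. Sub-peaks with identical coordinates were merged into 1 region with the values of its strongest sub-peak. The narrowest region was 150 bp wide in all 4 lists, and the lowest -log10 p was 2.00 or 2.01. No entry lay on the mitochondrial genome or a plasmid. The numbers in the peak names run 280 to 332 above the counts of sub-peaks, so the lists hold a part of the numbered peaks.

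Regions of the 0 min list that no region of the 180 min list of the same code overlapped by at least 1 bp were called lost, and the reverse were called gained. A lost or gained region is therefore a change of call at the authors' threshold and minimum width. Overlap counts were checked against bedtools 2.31.1 and were identical. Shares on chromosome IV were set beside the other 15 nuclear chromosomes and beside 10000 random sets of regions matched on decile of the list's -log10 q. Gene positions and names came from a RefSeq gene table of assembly R64, which sacCer3 represents. Strands were read from the systematic names, and each centromere was placed at the midpoint of the gap between the last left-arm and the first right-arm gene. Each gene list given by names yielded as many genes in that table as it has names, except the selection markers, whose 9 names gave 8 genes. The promoter window ran from 400 bp upstream to 100 bp downstream of the annotated start. A gene had a promoter peak when the summit of any sub-peak lay in that window. For 25 gene lists fixed before the data were examined, the share of promoter peaks lost was set beside 10000 random lists matched on -log10 q. The results of 1 of these lists are not reported here, though the counts of lists include it. Lists of tRNA and small nucleolar RNA genes were matched with all genes and the others with protein-coding genes.

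The genes named were chosen by a rule written before the data were examined. It takes, for each code, the 10 promoters with the highest -log10 q whose summit lay in the window in 1 list and whose window no region of the other list overlapped, in each direction. Genes that share a promoter peak count once. It adds up to 4 lost and 4 gained members of each gene list, up to 4 lost and 4 gained genes within 25 kb of CEN4, up to 4 lost and 4 gained in both codes, and SCW11, GAL1, TRP1, CSE4 and CTS1. NTH1 and RMD1, the genes beside CEN4, were added after the lists were seen. Genes given with a relative pileup in the other observations were also chosen after their values were seen.

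A further measure was added after the lists were seen. The caller's fold is (pileup + 1)/(background + 1) and its p is the upper Poisson tail of the pileup, so both the summit pileup and the local background were solved from the deposited fold and -log10 p. Between 99.1% and 99.8% of the recovered pileups were whole numbers within 0.05, where chance gives 10.0%. The recovered genome-wide background, the lowest value the local background takes and a measure of depth, was 413.8 at 0 min and 439.2 at 180 min in code 8, and 601.7 and 512.2 in code 11. A summit's relative pileup is its pileup divided by that background of its own list. The background covers all chromosomes, so more reads on 1 of them lower the relative pileup of the others. Summits of the 0 min and 180 min lists were matched when each was the other's nearest within 50 bp, and the log2 change of relative pileup was compared between chromosomes.

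The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. They were tested on simulated data. On 6838 simulated summits with the heights of the code 8 list, a log2 shift of 0.38 planted on chromosome IV was recovered as 0.38, and with none planted the recovered factor was 0.999. Both simulated times used the same summit positions, and fold and p came from the formula that the recovery inverts. No calling threshold was applied, and the planted rise did not change the genome-wide background. That run thus checks the arithmetic, and not the matching of summits or the effect of peak calling. In 200 simulated sets of 3599 regions with no effect, 1.5% lay above percentile 97.5. With a share planted 2.5 times as high on chromosome IV, 100% did. For lists of 10 promoters with a planted log2 shift of 0.15, 92.0% of 200 simulated lists lay above that percentile, against 2.0% with none. Those simulated shifts were independent of each other and of strength. In the data the shift depended on strength, and genes that share a promoter peak carry the same value, which the 2.0% does not cover.

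Alternatives varied the overlap rule, the -log10 q threshold, the length of the lists, the chromosome ends and ribosomal DNA, the counting of sub-peaks, the centromere window and the promoter window. A search for transcription factor motifs in lost and gained regions was not run, because no genome sequence was used here.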

Results

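Accessible chromatin was mapped by ATAC-seq in haploid MATa yeast of the S288c background. The design sets a control strain beside a strain whose chromosome IV centromere can be excised by Cre recombinase, before and 180 min after beta-estradiol. The 8 samples fall into 4 groups of 2, and 4 peak lists were analysed, for strain codes 8 and 11 at both times. In code 8 the lists held 3599 regions at 0 min and 3595 at 180 min, covering 2075.5 kb and 2033.7 kb. In code 11 they held 3699 and 3622 regions, covering 2145.6 kb and 2033.0 kb. The number of reads per sample is unknown. The background pileup recovered from the lists gives the relative depth, with code 8 at 413.8 and 439.2 and code 11 at 601.7 and 512.2 for 0 and 180 min. With 1 list per code and time there are no replicates, so differences are described without a test.

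The first comparison asks how far the map of open chromatin changed in 180 min. Most of it stayed in place in both codes. In code 8, 3433 of 3599 regions (95.4%, interval 94.7 to 96.0%) were kept, 166 were lost and 143 were gained. In code 11, 3504 of 3699 (94.7%, 94.0 to 95.4%) were kept, 195 were lost and 83 were gained. With lists of equal length, 145 were lost and 107 gained in code 11, and 163 and 144 in code 8. The regions that changed were weak and narrow. Lost regions had a median fold enrichment by the authors' caller of 1.74 in code 8 and 1.68 in code 11, against 3.29 and 3.18 for kept regions. Their median widths were 192 bp and 184 bp, near the 150 bp of the narrowest regions in the lists. Promoter windows held 73.2% of all 0 min regions in code 8 and 72.4% in code 11. They held 54.2% and 52.8% of the lost ones. Gene bodies held 7.25% and 8.16% of all 0 min regions and 28.3% and 30.3% of the lost ones.

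Individual sub-peaks within gene bodies were fewer at 180 min on the 15 chromosomes other than IV. Their number went from 1225 to 1043 in code 8 and from 1332 to 1173 in code 11. Promoter sub-peaks on the same chromosomes went from 3591 to 3436 and from 3687 to 3497. On chromosome IV the codes differed. Gene-body sub-peaks went from 171 to 248 in code 8 and from 188 to 171 in code 11, and promoter sub-peaks from 568 to 630 and from 574 to 548.

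The design centres on the centromere of chromosome IV, so this chromosome was set against the other 15. In code 8, chromosome IV lost few regions and gained many. It lost 6 of 484 regions (1.24%, 0.456 to 2.68%), the lowest share of the 16 chromosomes, while the others together lost 160 of 3115 (5.14%). It gained 51 of 521 (9.79%, 7.38 to 12.7%), against 92 of 3074 elsewhere (2.99%, 2.42 to 3.66%). The chromosome with the next highest gained share was VI, at 9.46%. Random region sets matched on -log10 q gained 2.50 to 5.18% and lost 2.69 to 5.37%, and chromosome IV lay at percentile 100 of the gained and percentile 0 of the lost shares. Of the 51 gained regions, 24 had their summit in a promoter window, 22 in a gene body and 5 elsewhere. Sub-peaks on chromosome IV went from 892 to 1038 (ratio 1.16), while the ratios of the other chromosomes ran from 0.884 on I to 0.989 on X. Regions per chromosome, taken relative to the rest, gave a ratio of 1.09 (0.962 to 1.24), the highest of the 16. That interval treats the counts at 0 and 180 min as independent, though all but 6 of the 484 regions were kept. It also takes the other chromosomes as free of error, so it does not measure the error of the ratio. The lower lost share turned to 0.102 points above the others when 50% reciprocal overlap was required.

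In code 11, chromosome IV was among the other chromosomes in every one of these measures. It lost 20 of 490 regions (4.08%, 2.51 to 6.23%) against 5.45% elsewhere, and gained 11 of 486 (2.26%, 1.14 to 4.01%) against 72 of 3136. These shares lay at percentiles 57.7 and 75.1 of matched random sets. Sub-peaks on chromosome IV went from 917 to 870 (ratio 0.949), rank 4 of the 16 from the highest, and the region ratio relative to the rest was 1.01 (0.893 to 1.15).

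**Figure D1:**
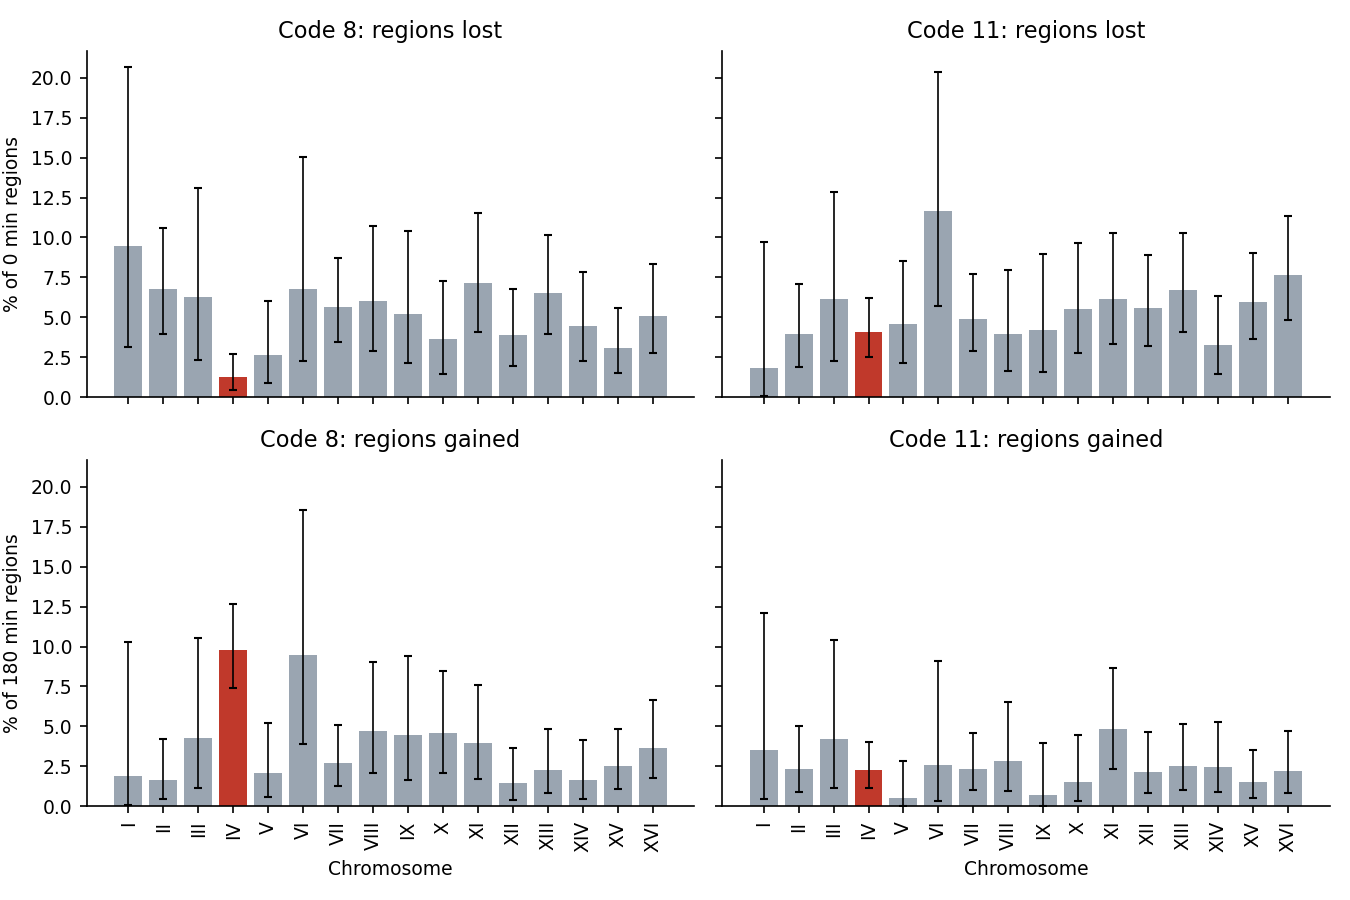
Share of regions lost (top, percent of 0 min regions) and gained (bottom, percent of 180 min regions) on each of the 16 chromosomes in code 8 (left) and code 11 (right); bars are shares, error bars exact 95% intervals for counting error, and chromosome IV is red. In code 8 chromosome IV has the lowest lost share, 1.24%, and the highest gained share, 9.79%.

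The height of the summits showed the same contrast. Among 5998 summits matched between the code 8 lists, the median chromosome IV summit moved from percentile 48.3 of relative pileup at 0 min to percentile 58.5 at 180 min. In code 11 it stood at 50.6 and 51.5 among 6223 matched summits. The median log2 change of relative pileup of the 832 chromosome IV summits in code 8 was 0.21 (SD over summits 0.16). The medians of the other 15 chromosomes lay between -0.07 and -0.03. The difference from the other chromosomes was 0.26, a factor of 1.20, and 811 of the 832 summits (97.5%) lay above the median of the other chromosomes. In code 11 the difference was 0.01, a factor of 1.01, with 436 of 813 summits (53.6%) above.

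The local background of code 8, which may itself include reads of nearby summits, moved together with the summits. On chromosome IV its median log2 change was 0.26, against -0.06 elsewhere, among summits whose local background at 0 min lay more than 5% above the genome-wide one. For the 292 chromosome IV summits with a relative pileup of at least 4, the log2 change of pileup was 0.18 and that of the fold over local background was -0.07, while the other chromosomes had -0.03 and 0.00. Promoter, gene-body and other summits of chromosome IV stood 0.24, 0.35 and 0.24 above the same classes elsewhere, in 545, 147 and 140 summits.

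**Figure D2:**
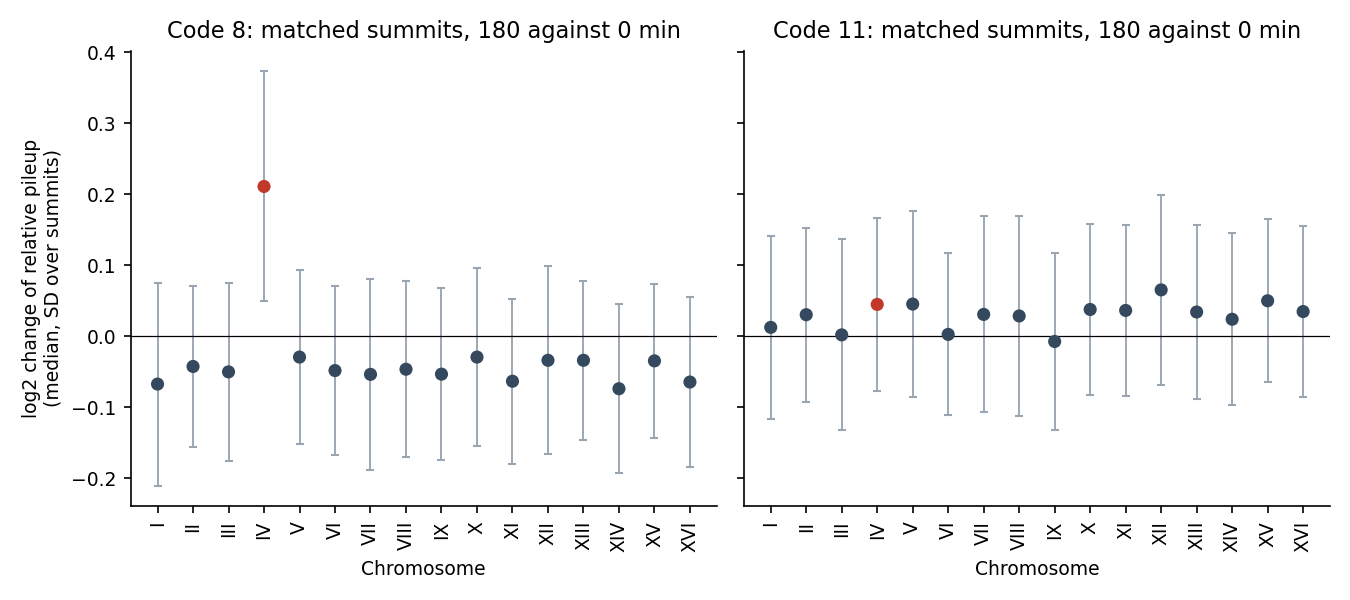
Median log2 change of relative summit pileup from 0 to 180 min on each chromosome in code 8 (left) and code 11 (right); error bars are the SD over summits and chromosome IV is red. In code 8 chromosome IV stands at 0.21 while the other 15 lie between -0.07 and -0.03; in code 11 it stands at 0.04.

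Along chromosome IV the change in code 8 was present from end to end and highest around the centromere. In 50 kb bins, 31 of 31 medians were above the other chromosomes, from 0.11 to 0.52 (log2), and the highest bin was 450 to 500 kb, next to CEN4 (midpoint of the gap 449748, sacCer3). The median was 0.56 in 11 summits within 10 kb of CEN4, 0.53 from 10 to 25 kb, 0.37 from 25 to 50 kb, 0.36 from 50 to 100 kb and 0.30 from 100 to 200 kb. Bins more than 200 kb away ran from 0.11 to 0.29. Windows of 50 kb around the other 15 centromeres ran from -0.03 to 0.08. Within 10 kb, 14 of the 15 stood above their own chromosome in code 8, with the highest median, 0.17, at CEN5, while 3 of the 15 did in code 11. In code 11, 18 of 31 bins were above the other chromosomes, and the median within 50 kb of CEN4 was -0.01 in 56 summits.

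The genes beside CEN4 followed this profile. RMD1 (YDL001W, chromosome IV 447984 to 449276) had a promoter summit with a relative pileup of 3.41 at 0 min and 4.70 at 180 min in code 8, and 3.55 and 3.48 in code 11. NTH1 (YDR001C, 450220 to 452475), a neutral trehalase, had 4.41 and 5.80 in code 8 and 4.13 and 4.33 in code 11. TRP1 (YDR007W, 461842 to 462516), of tryptophan synthesis, had 5.38 and 7.54 in code 8 and 5.06 and 5.58 in code 11. Within 25 kb of CEN4, 0 of 21 regions were lost in code 8, which allows a share of up to 14.3% by 3 counts (exact upper bound 16.1%), and 1 of 24 in code 11 (4.17%). The other 15 centromeres together lost 12 of 243 (4.94%) and 16 of 255 (6.27%). Within 50 kb of CEN4, 7 of 42 regions were gained in code 8 (16.7%, 6.97 to 31.4%) and 3 of 43 in code 11 (6.98%, 1.46 to 19.1%), against 13 of 438 (2.97%) and 10 of 452 (2.21%) at the other centromeres. Of the 29 protein-coding genes starting within 25 kb of CEN4, 22 had a promoter peak at 0 min in each code, and 0 lost and 0 gained one.

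**Figure D3:**
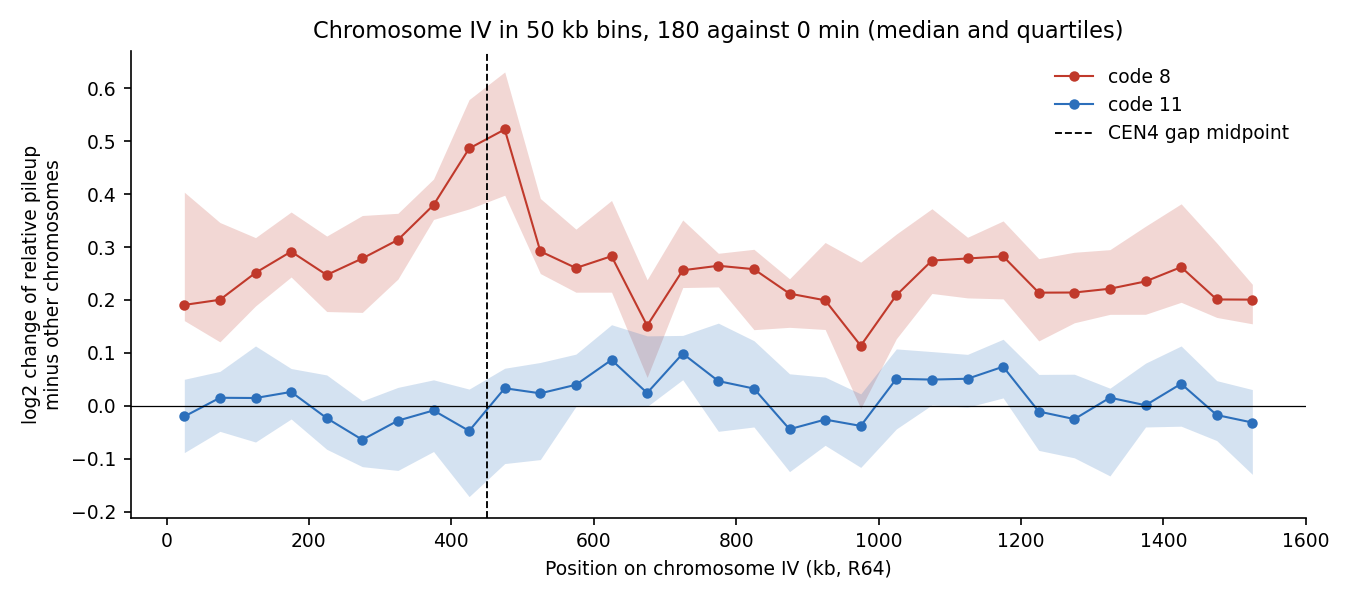
Median log2 change of relative summit pileup along chromosome IV in 50 kb bins, minus the median of the other chromosomes, for code 8 (red) and code 11 (blue); bands are quartiles over summits and the dashed line is the CEN4 gap midpoint. Code 8 lies above 0 in 31 of 31 bins and is highest, 0.52, in the bin from 450 to 500 kb.

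At promoters, 3885 of 6002 protein-coding genes (64.7%) had a peak at 0 min in code 8 and 3938 (65.6%) in code 11. In code 8, 145 genes lost and 135 gained a promoter summit. In code 11, 173 lost and 92 gained one. For 105 and 100 of those genes in code 8, and 120 and 52 in code 11, the other list had no region over the window at all. In code 8, 27 of these 100 gained genes lay on chromosome IV, and 3 of the 105 lost ones.

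The strongest promoter peaks called only at 0 min in code 8 were led by FUS2 (YMR232W, region XIII 736581 to 736776, upstream of the gene), a cell fusion gene of mating. Its -log10 q was 133 and its fold 2.44. ERP2, a vesicle coat cargo protein, had 119, and the divergent pair RKM1 and IPL1 had 101 (region XVI 157651 to 157828). IPL1 encodes the Aurora kinase that corrects kinetochore attachment. RCI50, HRD3, ROG1, the pair CKB1 and GET1, YNL092W, SHY1 and ADE17 followed, from 99.9 down to 85.2. None of these 10 promoters lay on chromosome IV. The median -log10 q of all regions was 315 at 0 min and 311 at 180 min in code 8, and 419 and 382 in code 11. The 10 strongest promoters in each direction, here and below, all lay under the median of their list.

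Of the 10 strongest promoter peaks called only at 180 min in code 8, 6 lay on chromosome IV. They were YDL057W (-log10 q 115), GCV1 (110), RAD9 (103), MTF2 (103), SAN1 (101) and YDR239C (101). RAD9, a DNA damage checkpoint adaptor, had its region at IV 903488 to 903679, just upstream of the gene. GCV1, a subunit of the glycine cleavage complex, had its region at IV 485433 to 485641. The others were XKS1 (141), which encodes xylulokinase, MCO32 (112), AMS1 (108), which encodes vacuolar alpha-mannosidase, and BEM3 (94.2).

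In code 11, SGE1, a membrane transporter near the right end of chromosome XVI, led the promoters called only at 0 min with a -log10 q of 137. RNH202 had 120, the pair SCC4 and SPT15 had 118 (region V 464896 to 465053), SNU56 118 and YDR239C 117. SCC4 belongs to the cohesin loader and SPT15 is the TATA-binding protein. RNH202, SNU56 and YDR239C were the 3 of these 10 promoters on chromosome IV. YDR239C was thus called only at 0 min in code 11 and only at 180 min in code 8. SYT1 with YPR096C and LEC1, PEX13, SSN3, MMP1 with MHT1, and BSC6 with RTC1 followed, from 112 down to 105. Promoters called only at 180 min in code 11 were led by XKS1 (164), VBA4 (119), HRD1 (117), ATG2 (108), AMS1 (105) and MLO1 (101). CIT3, KDX1, TPT1 and the pair JEM1 and SMC3 followed, from 96.8 to 90.0, and 1 of the 10 lay on chromosome IV.

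Changes shared by both codes were more frequent than in independent lists. Among 3805 genes with a promoter peak at 0 min in both codes, 99 lost it in code 8, 91 in code 11 and 34 in both, where independent lists share 2.37. Random sets matched on the -log10 q of code 8 shared 8 to 20, and the observed 34 lay at percentile 100. Strength in code 11 was not matched. Genes that share a promoter peak, such as SYT1, YPR096C and LEC1, were counted separately here, so the range of the random sets may be too narrow. Among 1984 genes with none at 0 min, 78 gained one in code 8, 53 in code 11 and 22 in both, against 2.08 for independent lists. That value is not matched on strength, which raised the chance value of the lost genes from 2.37 to a median of 13. The strongest lost in both were YPR084W, NPL6 (a subunit of the RSC chromatin remodeller), SCM4 and SSN3 (the kinase of the Mediator complex), with -log10 q of 71.6, 71.6, 68.1 and 67.9 in code 8 and 101, 88.5, 104 and 108 in code 11. The strongest gained in both were XKS1, AMS1, MLO1 and GCV1, with 141, 108, 79.4 and 110 in code 8 and 164, 105, 101 and 77.8 in code 11.

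Most of the fixed gene lists lost few or no promoter summits, where all protein-coding genes lost 3.73% in code 8 and 4.39% in code 11. Some short lists lost a larger share, such as 2 of 11 kinetochore and checkpoint genes in code 8. In code 8, 15 of 25 lists lost 0 promoter summits, and in code 11, 18 did. Among 25 lists in each code, only tRNA genes in code 11 passed percentile 2.5 or 97.5 of matched random lists. They lost 1 of 210 (0.476%), at percentile 1.64, which counts ties only in part. The share itself equalled the lower end of the central 95% of the random lists (0.476 to 4.29%), so it was not outside that range. It was 0% with any region over the window counted and 7.50% with a window of 1000 bp upstream. Ribosomal protein genes lost 4 of 125 in code 8 (percentile 86.7) and 2 of 125 in code 11 (43.2). The 4 were RPP2A, RPL30, RPL32 and RPS26A, and at all of them a 180 min region still lay over the window without a summit in it. The 2 in code 11 were RPS29B and RPL32, and 1 was gained, RPL13A, again with a region over the window in the other list. Amino acid synthesis lost 2 of 15 in code 8, LEU4 and ARG4 (percentile 97.2), and 0 of 15 in code 11, where ASN1 gained one. ARG4 had no region over the window at 180 min, while LEU4 and ASN1 had one in both lists of the code. Kinetochore and checkpoint genes lost 2 of 11 in code 8, IPL1 and MIF2 (percentile 95.7), both without a region over the window, and 0 of 10 in code 11. Pheromone response genes lost 1 of 11 in code 8, FUS2, and 0 of 12 in code 11. Condensin, cohesin and Smc5/6 genes lost 0 of 7 in code 8. In code 11 they lost 1 of 8, SCC4, and gained SMC3, and the lost share of 12.5% was 22.2% with any region over the window counted.

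Late G1 genes lost 0 of 12 in both codes. They gained 4 in code 11, RNR1, HO, SMC3 and CLN2, of which SMC3 had no 0 min region over its window. Mitotic genes of the CLB2 cluster lost 0 of 9 and gained 0 in both codes. Histone genes (9), heat shock genes (11), galactose genes (6), phosphate genes (6) and MATa-specific genes (7) kept all their promoter peaks in both codes, as did ribosome biogenesis genes (19) and the selection markers. DNA damage genes lost 0 of 9 and gained RNR2 in both codes, with a 0 min region already over its window. General stress genes lost 0 of 12 and gained GAD1 in code 8, and lost TFS1, 1 of 12, in code 11. Glucose-repressed genes lost JEN1 and gained PCK1 and FBP1 in code 8, and lost 0 of 8 in code 11. Glycolysis genes lost FBA1, 1 of 11, in code 8, and gained ENO1 in code 11. At TFS1, JEN1, PCK1, FBP1, FBA1 and ENO1 the other list had a region over the window without a summit in it, and at GAD1 it had none.

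The groups that mark other cell types carried few promoter peaks. Of 4 MATalpha-specific genes 1 had a peak at 0 min in each code, and of 10 meiotic genes 2 did. MF(ALPHA)2 (-log10 q 5.57) and NDT80 (79.0) gained a promoter summit in code 11, and a 0 min region already lay over the window of MF(ALPHA)2. Subtelomeric genes lost 5 of 117 in code 8 (4.27%, percentile 38.7), among them FDC1, FDH1, PGA3 and GTT2, and gained 7, among them YOR389W, YJR154W, DFP4 and RMD8. In code 11 they lost 12 of 121 (9.92%, percentile 95.5), among them SGE1, MMP1 with MHT1, COS4 and GTT2, and gained 1, ARN2. Small nucleolar RNA genes lost 3 of 58 and 2 of 55, and tRNA genes lost 2 of 209 in code 8 and gained 9 there and 13 in code 11. At the 2 lost tRNA genes, and at the 4 gained ones with the highest -log10 q in each code, the other list had a region over the window without a summit in it.

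Of the 5 genes chosen in advance for the study's theme, TRP1 had a promoter summit in all 4 lists, and the other 4 had none that could be lost. The windows of SCW11 and CTS1, daughter-cell genes of early G1, were overlapped by a region in all 4 lists, with summits 570 to 574 bp upstream. The fold at SCW11 was 2.90 and 3.12 in code 8 and 3.03 and 3.34 in code 11, and at CTS1 3.73 and 3.75 and 3.86 and 4.46. GAL1 had its summit 401 to 404 bp upstream, with folds of 5.02, 4.67, 4.48 and 4.78 in the same order. CSE4, the centromeric histone H3 gene, had no region over its promoter window in any of the 4 lists.

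Between codes, the lists were nearly the same at 0 min. Of the code 8 regions 98.1% (97.6 to 98.5%) were overlapped by a code 11 region, and of the code 11 regions 95.5% (94.7 to 96.1%) by one of code 8. At 180 min the shares were 96.3% and 95.8%. The code 8 regions without a counterpart at 180 min were concentrated on chromosome IV, with 50 of 521 (9.60%, 7.21 to 12.5%) against 83 of 3074 elsewhere (2.70%, 2.16 to 3.34%). At 0 min these shares were 10 of 484 (2.07%) and 59 of 3115 (1.89%). In the reverse direction, 3 of 486 code 11 regions on chromosome IV lacked a counterpart at 180 min (0.617%, 0.127 to 1.79%), against 150 of 3136 elsewhere (4.78%).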

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

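Several measures of chromosome IV fell on opposite sides of 0 or 1 in the 2 codes, and the difference was not tested because there is 1 list per code and time. The gained share minus that of the other chromosomes was 6.80 percentage points in code 8 and -0.0325 points in code 11. The value of code 11 lay near 0 and changed sign under alternatives. It was 0.0843 with a -log10 q of at least 10 in the list counted and 0.140 with every sub-peak counted. Sub-peaks on chromosome IV at 180 min over 0 min had a ratio of 1.16 in code 8 and 0.949 in code 11, where the other 15 together had 0.937, so chromosome IV moved with the others there. Regions on chromosome IV had ratios of 1.08 and 0.992, where the other 15 together had 0.987 and 0.977. Relative to the rest, both codes lay above 1, at 1.09 and 1.01. The median shift of relative pileup within 50 kb of CEN4 was 0.486 (log2) in code 8 and -0.0108 in code 11. The tests below were chosen only after the result was seen, except those of the summit classes and of the strength of the lost sub-peaks. The class test took the place of an earlier one on the p threshold. That one was dropped unrun, because the 150 bp minimum width also bears on which regions are called.

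Chromosome IV gained regions and stood higher than the other chromosomes in the 180 min list of code 8. The 180 min list was the deeper one by its background (ratio 1.06). Depth as the cause is argued against by the other 15 chromosomes, whose median ratio of sub-peaks was 0.925. For opening of promoters alone, the fold over local background at strong summits stood at -0.0666 (log2) relative to the other chromosomes. That value cannot decide, because the samples hold no separate library for the background, which may include reads of nearby promoter peaks. Gene-body summits also stood higher than the same class elsewhere, by 0.352, so the rise was not limited to promoter windows. More reads from all of chromosome IV, as more copies of it would give, would move all summit classes alike, but the medians of promoter, gene-body and other summits spanned 0.115, above the bound of 0.1 set beforehand, which by itself counts against this explanation. The classes were not matched on strength, and the shift also depended on it, with medians of 0.28 on chromosome IV against -0.06 elsewhere at relative pileups of 1.5 to 2, and 0.19 against -0.01 above 6. An interval from 1000 resamples of the summits (0.0859 to 0.159), added only after that value was seen, includes the bound, so the class test left the explanation open. As the cause of the whole rise it is argued against by the uneven profile along chromosome IV. The median there was 0.486 within 50 kb of CEN4, against at most 0.29 in bins more than 200 kb away. The excision named in the design was left open, untested because no label links code 8 to a strain.

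Along chromosome IV, the difference in code 8 was largest around CEN4. One factor for the whole chromosome is argued against by the median of 0.486 within 50 kb of CEN4, where the highest bin more than 200 kb away had 0.29. Reads from an excised circle or construct next to CEN4 would stay close to it, but summits 25 to 100 kb away stood at 0.362. A general property of regions around centromeres is argued against as the whole cause by the other 15, of which the highest within 50 kb, CEN2, had 0.0845. Within 10 kb, 14 of the 15 stood above their own chromosome in code 8, by up to 0.15 (log2) against 0.30 at CEN4, but 3 of the 15 did in code 11, so a smaller part shared by centromeres stays open for code 8 and was not seen at most centromeres in code 11.

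The other 15 chromosomes had fewer sub-peaks at 180 min than at 0 min in both codes. Lower read depth at 180 min is argued against in code 8, whose background ratio of 180 over 0 min was 1.06, and cannot be told apart from time in code 11, where it was 0.851 in a single pair of lists. Weak summits falling under the threshold would put most lost sub-peaks among the weakest 10% of their list. Here a sub-peak was lost when no 180 min summit lay within 100 bp. These were 730 of 5946 in code 8 and 723 of 6176 in code 11. Only 213 and 241 sub-peaks over all chromosomes had no overlapping 180 min region, so most of those tested lay in regions still called. Those tested had a median percentile of -log10 q of 12.6 in code 8 and 13.0 in code 11. Both lay between the bounds of 10 and 25 set beforehand. The weakest 10% of the list held 42.5% and 42.3% of them, and the weakest 25% held 74.5% and 72.6%. The test did not decide, because it mixes summits under the threshold with summits lost within a region still called. No biological explanation was tested for this pattern.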

How the results depend on the processing

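The alternatives were planned, except those on the relative pileup and those without chromosome IV, which were chosen after seeing the data. Of the values under alternatives, 181 stayed within their interval or within 1.5 times the count, 58 moved further and 1 reversed. No paired analysis was possible because the lists carry no replicate numbers, and for the same reason no replicate could be left out. The planned motif search was not run without a genome sequence, and including mitochondrial and plasmid regions changed nothing because the lists hold none.

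The gained share of chromosome IV minus that of the other chromosomes in code 8 kept its sign under all 7 alternatives, from 4.85 to 7.77 points. Its lost share minus theirs, -3.90 points, reversed to 0.102 with 50% reciprocal overlap and was -1.32 with summits within 100 bp, and the cause was not tested. In code 11, 50% reciprocal overlap moved these differences to -3.00 for lost and -1.65 for gained regions. That overlap rule left 91.0% of 0 min regions kept in code 8, with 324 lost and 320 gained, and 91.9% in code 11, with 300 lost and 223 gained. Summits within 100 bp gave 91.8%, 294 and 290 in code 8 and 92.0%, 296 and 219 in code 11. Both rules are stricter than 1 bp of overlap. Counting every sub-peak gave 96.9% kept in code 8 and 96.6% in code 11, and lists of equal length 96.0% in code 11. The lists hold 6838 and 6588 sub-peaks in code 8 and 7093 and 6654 in code 11. Without chromosome IV, code 8 gained 92 regions.

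The relative pileup of chromosome IV in code 8, 0.26 (log2) above the others, was 0.211 at summits with a relative pileup of at least 4 and 0.237 without 100 kb on each side of CEN4, where it was highest. In code 11, 0% of regions within 10 kb of CEN4 were lost.

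Of the regions shared between codes, 50% reciprocal overlap left 95.03% of code 8 and 92.5% of code 11 at 0 min, and 92.6% and 91.9% at 180 min. Summits within 100 bp left 95.3% and 92.8%, and 93.2% and 92.5%. Counting every sub-peak gave 98.9% and 97.1%, and 97.7% and 96.9%. Lists of equal length gave 97.0% and 96.7% at 0 min.

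With any region over the promoter window counted, ribosomal protein genes lost 0.741% in code 8, general stress genes 0% in code 11, glucose-repressed and glycolysis genes 0% in code 8, and tRNA genes 0% in both codes. Condensin, cohesin and Smc5/6 genes in code 11 lost 22.2%, within the interval of their 12.5%. With a window of 1000 bp upstream, ribosomal protein genes lost 0% in both codes, general stress and small nucleolar RNA genes 0% in code 11, and glucose-repressed and glycolysis genes 0% in code 8. Late G1 genes lost 5.88% in code 11 with that window, against 0%. tRNA genes lost 9.65% in code 8 and 7.50% in code 11 with that window, which leaves out the gene itself, and the cause was not tested. The effect of read depth itself was not varied. Lost regions had a median width of 192 bp in code 8, near the 150 bp of the narrowest regions, so a region no longer called is not shown to have lost its signal.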

Other observations

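The height of matched promoter summits, relative to the median of the chromosomes other than IV, differed between gene groups. Members on chromosome IV were left out, except in the list around CEN4. The lists were compared with 10000 random lists of protein-coding promoters matched on relative pileup, a comparison chosen only after the data were seen. The 23 lists with at least 3 matched promoters were compared in each code. Phosphate genes stood high in both codes, with a median log2 shift of 0.16 in code 8 (percentile 99.9, 3 of 5 members above 0) and 0.18 in code 11 (99.8, 5 of 5). PHM8 had a relative pileup of 5.79 at 0 min and 6.26 at 180 min in code 8, and 6.20 and 7.17 in code 11. VTC3, of the polyphosphate synthesis complex, had 3.63 and 3.93, and 3.66 and 4.13. SPL2 had 7.67 and 7.09 in code 8, and 7.20 and 8.44 in code 11.

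Pheromone response genes stood low in code 8, with a median shift of -0.11 (percentile 0.65, 1 of 10 members above 0), and at 0.02 in code 11 (percentile 79.2, 8 of 11 above 0). FUS1 had a relative pileup of 3.60 and 3.07 in code 8 and 3.42 and 3.71 in code 11. SST2 had 3.46 and 2.98 in code 8 and 3.41 and 3.53 in code 11. The exception in code 8 was FAR1, the cyclin-dependent kinase inhibitor of the pathway, with 2.96 and 3.13. Ribosomal protein genes stood at 0.02 in code 8 (percentile 19.9) and 0.11 in code 11 (percentile 100), where 83 of 106 promoters were above 0. General stress genes had 0.05 in code 8 (79.3) and 0.15 in code 11 (99.4), where the matched random lists ran from -0.01 to 0.13. TPS1, of trehalose synthesis, had 10.6 and 11.2 in code 8 and 10.1 and 12.1 in code 11. Glucose-repressed genes had 0.11 in code 8 (99.4) and lay at percentile 58.1 in code 11, and CLB2 cluster genes 0.09 (98.4) and 0.03 (64.5). Subtelomeric promoters stood at -0.05 in code 8 (percentile 0) and -0.04 in code 11 (1.09). In code 11, tRNA genes stood at -0.02 (percentile 0) and small nucleolar RNA genes at -0.04 (0.13). Differences between the codes in these lists were not tested.

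Heat shock genes as a list stood at 0.05 in code 8 (percentile 84.3, 6 of 10 members above 0) and 0.01 in code 11 (4.98, 7 of 10). The promoters of SSA4 and HSP78, which belong to the general stress list, stood lower at 180 min in both codes. Most members of that list off chromosome IV went the other way, with 6 of 9 above 0 in code 8 and 7 of 8 in code 11. SSA4, an HSP70 chaperone on chromosome V, had a relative pileup of 8.53 and 7.20 in code 8 and 8.63 and 7.72 in code 11. HSP78, a mitochondrial chaperone on chromosome IV, had 5.73 and 5.18 in code 8 and 5.70 and 4.78 in code 11. Relative to the median of the other chromosomes, its log2 shift in code 8 was -0.10, while the median of chromosome IV was 0.26. Both genes were chosen after their values were seen.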
